A study of Mus musculus with 8 samples.

How the data were processed

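The series followed the reprogramming of mouse embryonic fibroblasts (MEFs) into induced pluripotent stem cells (iPSCs). The cells carried doxycycline-inducible copies of Pou5f1, Sox2, Klf4 and Myc (OSKM), per the labels' protocols. Long RNA libraries were made at 4 stages, which were MEFs before induction (day 0), cells at day 3 and day 6 of induction, and established iPSCs. Per the labels' protocols, ribosomal RNA was removed before library construction and no selection for polyadenylated RNA is described. Transcripts without a poly(A) tail, such as those of replication-dependent histones, can therefore be present in the libraries. The labels' protocols place reprogramming in a serum-replacement medium with LIF and the GSK3 inhibitor CHIR99021, and the medium of the MEFs before induction is not given in the sources used here. A difference between MEFs and day 3 can therefore hold an effect of medium as well as of induction.

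The deposited table gives 1 value per gene and stage in FPKM (fragments scaled to gene length and to library size), per the file headers. HISAT2, Cufflinks and the mouse genome build mm9 are named in the submitters' processing notes, with no version or role. The strand setting, the gene models, the filters and any pooling of cultures are not given in the sources used here. An FPKM value is relative to the other RNAs of its library, so a difference between libraries is one of share and not of molecules per cell. Reads of the induced copies and of the resident genes are not separated in a table of genes.

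The table held 17922 rows, of which 17838 carried an Ensembl identifier and 84 did not. Of those identifiers, 17320 (97.1%) were found in a reference table of current gene names. Gene symbols are those of the table. A symbol stood on more than 1 row in 199 rows. In the lists and among the named genes such a gene was represented by its highest row. Counts of genes by the rule or by stage took every row. The symbol 2810453I06Rik thus entered the counts of day 3 against MEFs both as higher and as lower. The reference annotation in hand was on assembly GRCm38 and not on mm9, so no coordinates are given. It was used for gene classes and for which genes overlap, and 16470 rows matched a protein-coding gene and 249 a long noncoding RNA gene. At least 1 FPKM in at least 1 library was reached by 13101 rows, and 184 rows were at 0 in all libraries.

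Sequencing depth is not stated in the table. The FPKM columns summed to between 438130 and 486609. The worth of the lowest values gave a rough relative depth. Among rows under 0.06 FPKM in both libraries, the most frequent ratio of values put the number of fragments of the day 3 library at 0.65 of that of the MEF library, the day 6 library at 1.04 and the iPSC library at 1.02. Low values were thus least precise at day 3. An exact 0 in such a table can be a failed estimate, and a gene at 0 is described as listed at 0. Some rows of genes that every cell uses had very low values, among them Hmgcs1 with 0.0219 FPKM in MEFs, so a low value of a single row can also be an estimation failure.

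Each group had 1 library, so no test, p-value or error across libraries was possible. Comparisons rest on a fixed rule of size. Values were put on the scale log2(FPKM + 1), on which differences of weakly expressed genes are understated. A gene was called higher or lower when the difference was at least 1 (2-fold) and the higher value was at least 1 FPKM. The main contrasts were day 3 against MEFs, day 6 against day 3, iPSCs against day 6 and iPSCs against MEFs. Genes were assigned to the library with their highest value when their highest and lowest log2 values differed by at least 1. A gene was called transiently high when day 3 or day 6 exceeded both MEFs and iPSCs by at least 1. It was called transiently low only when day 3 and day 6 were both below MEFs and iPSCs by at least 1.

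Gene lists, 33 in number, were fixed before the data were examined. They covered pluripotency, fibroblast, mesenchymal, epithelial and contractile genes, cell cycle and metabolic pathways, chromatin and RNA regulators, gene families and markers of other cell types. For each list the members higher, lower and within the rule were counted, among members with at least 1 FPKM in any library. The median difference was placed among 10000 random lists of the same size, matched in 20 bins on mean log2(FPKM + 1) over all 4 libraries. This percentile describes these libraries and is not a test, since genes of a list vary together. In contrasts without iPSCs, lists high mainly in iPSCs are thus matched with genes that can be more strongly expressed in the compared libraries. The median of each list's members is the main value. A further 4 lists (NRF2 targets, aryl hydrocarbon receptor targets, abundant keratinocyte genes and cartilage genes) were added after the largest differences had been seen. Named genes are members of the lists and, per contrast, the 10 genes with the largest positive and the 10 with the largest negative difference among rows of at least 5 FPKM in the higher library. Predicted, clone and short RNA names were left out of the ranking.

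Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The rule and the list percentile were tested on simulated data made from the MEF library, in the form of the day 3 against MEFs contrast, with log2 noise of SD 0.15. The rule was run over 11645 genes and the list percentile over 13101. Of 100 genes changed by 1.5 on the log2 scale 99 were recovered, as were 100 of 100 changed by 3, and 0 unchanged genes were called. A list of 20 genes shifted by 0.5 had a median of 0.50 and percentile 100, and 5 of 100 unshifted lists lay outside the central 95% of random lists. The changed and shifted genes were drawn from those at 10 FPKM or more in MEFs. All genes had the same noise, without counting noise or a lower depth at day 3. Such noise makes a false call almost impossible. How the rule performs on weakly expressed genes was therefore not tried. The alternatives tried were pseudocounts of 0.1 and 5, other minimum values, 3 rescalings, a log2 difference of 2, means in place of medians, unmatched random lists and the removal of predicted and clone names.

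The 4 small RNA libraries were not analysed here, and neither were circular RNAs. Of 42 long noncoding RNAs fixed for the lists, 1 was found in the table and the others were not analysed here. Several other list members, among them Dppa3, Krt5 and Meg3, were also not analysed here.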

Results

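Gene expression was measured by RNA sequencing in 4 long RNA libraries, 1 each from MEFs (day 0), from the same kind of culture at day 3 and day 6 after induction of OSKM, and from iPSCs. The comparisons address how the transcriptome differed between successive stages of reprogramming. There were no replicate libraries, so differences carry no error and none was tested. A robust SD of the log2 difference over genes at 10 to 100 FPKM gives a scale for them. It was 0.147 between MEFs and day 3, 0.177 between day 3 and day 6, and 1.188 between day 6 and iPSCs, and it includes both noise and real differences. Values are FPKM, and differences are on the log2(FPKM + 1) scale.

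The first 3 libraries resembled each other and the iPSC library stood apart. Across 13101 genes, which are not independent replicates, the Pearson correlation of log2 values was 0.994 between MEFs and day 3 and 0.987 between MEFs and day 6. It was 0.650 between MEFs and iPSCs and 0.666 between day 6 and iPSCs. By the rule of size, 20 genes were higher and 6 lower at day 3 than in MEFs, of 11740 compared. Between day 3 and day 6, 54 genes were higher and 47 lower at day 6, of 11817 compared. With pseudocounts of 0.1 and 5 these were 131 and 126, then 16 and 11. Between day 6 and iPSCs, 2645 genes were higher and 3034 lower in iPSCs, of 12951 compared, and after rescaling to the same upper quartile 2982 were higher and 2806 lower, so which side held more genes depended on the scaling.

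**Figure D1:**
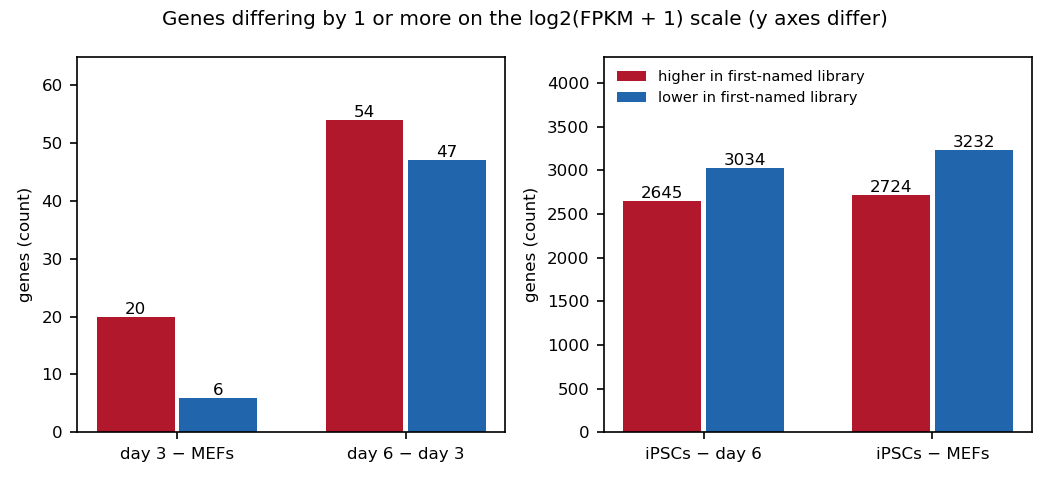
Number of genes (y axis, count) higher (red) or lower (blue) by at least 1 on the log2(FPKM + 1) scale in the first-named library of each contrast (x axis), with 1 library per group. The left panel, on its own y axis, holds 20 and 6 genes for day 3 and 54 and 47 for day 6, and the right panel holds 2645 and 3034 genes for iPSCs against day 6 as deposited (2982 and 2806 after upper-quartile rescaling).

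The induced factors differed in how far they departed from MEFs. Pou5f1 (ENSMUSG00000024406), the gene of OCT4, was at 0.226 FPKM in MEFs, 3.03 at day 3, 8.56 at day 6 and 740 in iPSCs. Sox2 was at 0.411, 1.19, 2.03 and 88.7 FPKM. Klf4 was at 10.6, 13.7, 12.1 and 17.3 FPKM and Myc at 16.8, 21.2, 22.8 and 1.83 FPKM, so neither reached the rule at day 3 or day 6. Of the 4 factors, 1 (Pou5f1) was past the rule at day 3 against MEFs and 1 (Pou5f1) at day 6 against day 3. For day 6 against MEFs, 2 were past it (Pou5f1 and Sox2).

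At day 3 the largest differences from MEFs were in few genes. Slurp1, which encodes a secreted protein of stratified epithelia, was at 0.143 FPKM in MEFs and 12.2 at day 3. Aldh3a1, an aldehyde dehydrogenase abundant in the cornea, was at 0.360 and 9.97. The mesothelial surface gene Msln was at 3.55 and 10.3, and Tcf7l1, a transcription factor of the Wnt pathway, at 2.28 and 8.12. The zinc finger genes Zfp35 and Zfp618 were at 3.53 and 7.28 FPKM in MEFs, at 9.21 and 17.2 at day 3, and at 3.58 and 6.95 at day 6. Npn2 was listed at 0 in MEFs and at 239 FPKM at day 3, 74.3 at day 6 and 24.8 in iPSCs. Among the lower genes, Arhgap27 was at 5.75 FPKM in MEFs and 2.00 at day 3, and Zfp691 at 5.69 and 2.19. The counts of this contrast depended on weakly expressed genes. With a pseudocount of 5 they were 6 higher and 2 lower, and without predicted, clone and short RNA names 13 and 3.

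Between MEFs and day 3 few list members passed the rule, while the medians of 7 of the 33 lists lay above and of 6 below the central 95% of random lists. Of 30 pluripotency genes 0 passed the rule (median difference 0.01, percentile 66.1 among random lists), and of 27 fibroblast matrix and surface genes 1 did, the proteoglycan gene Dcn with 1.84 and 4.76 FPKM. All 16 mesenchymal regulators and all 26 epithelial genes were within the rule. The serum response factor (SRF) target and contractile list had a median of -0.24 at percentile 0, with 13 of 14 members below their MEF value. The cell cycle list had a median of 0.13 at percentile 100, with 22 of 24 above. The mitochondrially encoded genes had a median of 0.33 at percentile 100 and the ribosomal protein genes one of -0.14 at percentile 0.13, all within the rule. The interferon response list had a median of -0.26 at percentile 0, and the macrophage and leukocyte markers, of cells that can accompany fibroblasts, one of -0.25 at percentile 0.02. Lyz2, a lysozyme of macrophages, was at 52.9 FPKM in MEFs and 36.2 at day 3.

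At day 6 the genes above day 3 included detoxification, antioxidant and epidermal genes. Only the epidermal genes had a list fixed before the data were examined, and the others were read from the largest differences. Aldh3a1 was at 9.97 FPKM at day 3 and 70.2 at day 6, and Slurp1 at 12.2 and 67.9. Gsta4, a glutathione transferase, was at 6.78 and 29.7, Srxn1, a sulfiredoxin, at 18.0 and 49.4, and Ahr, the aryl hydrocarbon receptor, at 8.48 and 23.5. The iron-binding lipocalin Lcn2 was at 3.33 and 17.5, the myelin and lymphocyte protein gene Mal at 4.85 and 15.0, and Igfbp3, an IGF-binding protein, at 9.07 and 31.3. Of 6 epidermal genes, 3 were higher at day 6, with a list median of 1.23 at percentile 100, or 0.45 when members under 1 FPKM are kept. Krt14 was at 0.575 and 4.66 FPKM, Krt16 at 0.940 and 5.27, and Sprr1a, a component of the cornified envelope, at 2.36 and 8.43. Against MEFs in place of day 3, 91 genes were higher and 69 lower at day 6.

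Contractile genes stood among the lower genes at day 6. All 14 members of the SRF target and contractile list were below their day 3 values, 2 of them past the rule, with a median of -0.45 at percentile 0. Acta2, smooth muscle actin, was at 2534 FPKM in MEFs, 2132 at day 3 and 1010 at day 6. Calponin, encoded by Cnn1, was at 146, 104 and 46.8, and Tagln (1611, 1348 and 794 FPKM) was within the rule between day 3 and day 6. Genes of another cell type went the same way, with cartilage genes at a median of -0.68 and percentile 0 and 11 of 13 below day 3, in a list added after the largest differences were seen and without the 2 genes that prompted it. From the ranking, the smooth muscle myosin Myh11 was at 10.3 FPKM at day 3 and 2.44 at day 6, Myom1 at 38.8 and 14.3, and the cell adhesion gene Mcam at 29.3 and 9.98. Apol7d was at 10.6 and 1.02, and Supv3l1, a mitochondrial RNA helicase, at 31.5 and 8.39.

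The cholesterol and glycolysis lists had medians outside those of random lists at day 6, with all members within the rule, and the oxidative phosphorylation list did not (0.02, percentile 68.2). All 18 cholesterol biosynthesis genes were below their day 3 values (median -0.41, percentile 0), among them Fdps with 60.8 and 38.4 FPKM and Insig1 with 29.1 and 18.1. The glycolysis list had a median of 0.29 at percentile 100, with 13 of 17 members above day 3, and the cell cycle list 0.25 at percentile 100, with 22 of 24 above. The interferon list was 0.31 above day 3 at percentile 100, with the macrophage and leukocyte markers at 0.10 and percentile 91.7. The interferon list had been below MEFs at day 3. For day 6 against MEFs its median was 0.21 (percentile 99.7), with 7 members above and 6 below. The p53 target and senescence list was at 0.14 (percentile 99.7), and its cell cycle inhibitor Cdkn1a was at 66.1, 76.5 and 76.0 FPKM in MEFs, at day 3 and at day 6.

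Pluripotency genes remained near their MEF levels through day 6. Of 30 members, 0 were higher and 1 was lower at day 6 than at day 3, which was Klf2 with 25.1 and 10.2 FPKM. Nanog was at 0.398 FPKM in MEFs, 0.270 at day 3 and 0.241 at day 6, and Esrrb at 0.0629, 0.0415 and 0.0633. Of 26 epithelial genes 1 was higher at day 6 than at day 3, the keratin gene Krt8 with 0.356 and 2.22 FPKM. E-cadherin, encoded by Cdh1, was at 0.0818 FPKM in MEFs, 0.431 at day 3 and 1.14 at day 6, a difference from MEFs of 0.98 that lay just under the rule. Epcam was at 0.0265, 0.0262 and 0.122 FPKM. All 27 fibroblast matrix and surface genes and all 16 mesenchymal regulators were within the rule between day 3 and day 6. Col1a1 was at 940, 1257 and 1453 FPKM and Vim at 3537, 3021 and 2781.

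**Figure D2:**
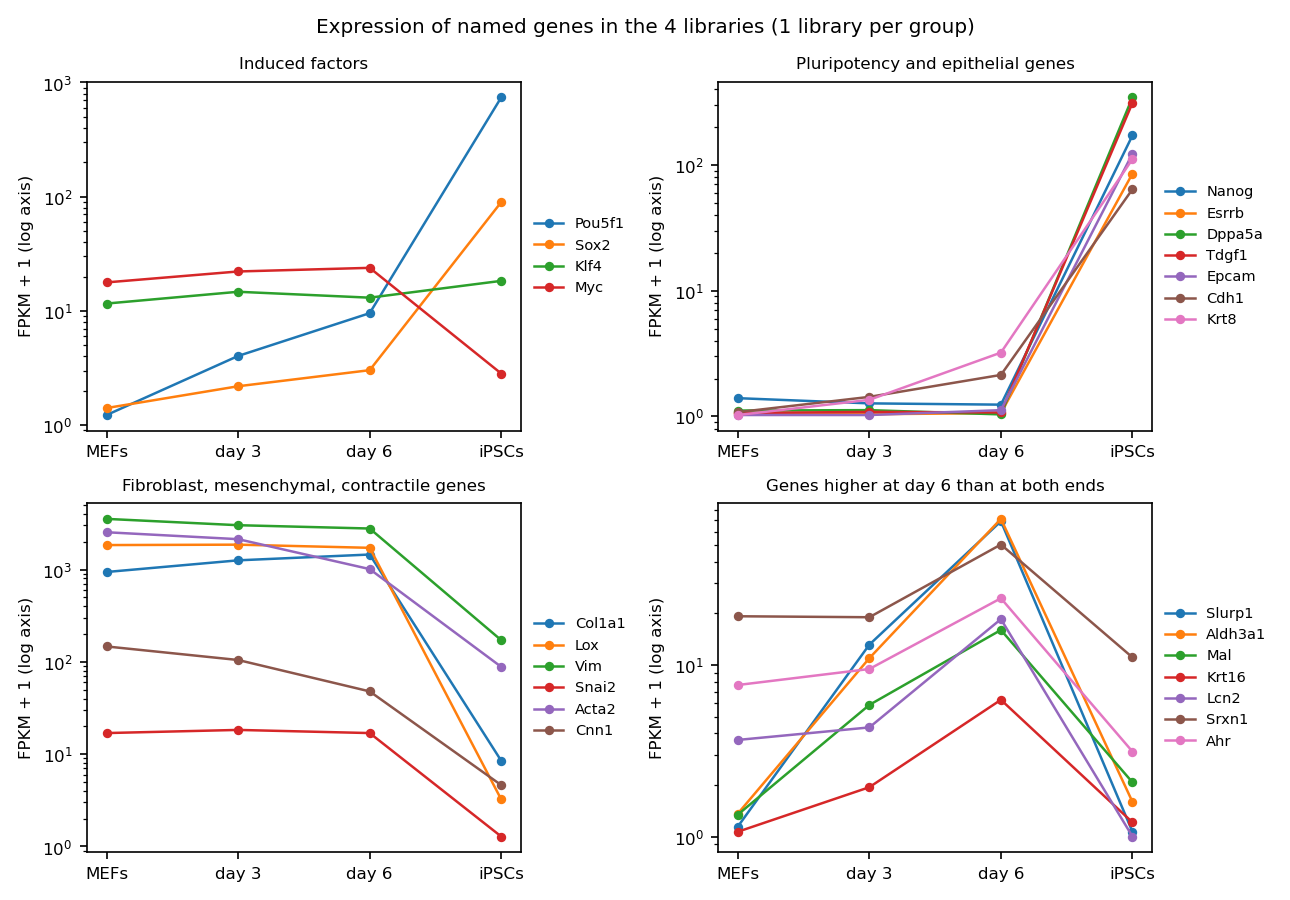
FPKM + 1 on a log y axis for named genes in the MEF, day 3, day 6 and iPSC libraries (x axis), where each point is 1 library and lines only join the points of a gene. Pou5f1 lies at 3.03 FPKM at day 3 and 740 in iPSCs, most pluripotency and epithelial genes stand apart only in iPSCs, Acta2 is at 1010 FPKM at day 6, and Slurp1 and Aldh3a1 peak at day 6 with 67.9 and 70.2 FPKM.

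In iPSCs, pluripotency genes were high and fibroblast genes low. Of 30 pluripotency genes, 29 were higher in iPSCs than in MEFs, with a median of 4.32, and the other, Klf2, was at 28.9 FPKM in MEFs and 14.2 in iPSCs. Nanog was at 171 FPKM, Dppa5a at 344, Tdgf1, a Nodal co-receptor, at 311 and Zfp42 at 87.8. Of 27 fibroblast matrix and surface genes 26 were lower, with a median of -5.63. The crosslinking enzyme gene Lox was at 1840 FPKM in MEFs and 2.23 in iPSCs, Col5a2 at 1985 and 2.20, and Bgn at 1110 and 2.06. Pdgfra was within the rule at 6.25 and 3.99. The largest negative difference was that of Mgp, matrix Gla protein, with 4832 and 2.09 FPKM.

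Mesenchymal and epithelial lists went in opposite directions between MEFs and iPSCs. Of 16 mesenchymal regulators 15 were lower (median -3.34), with Snai2 at 15.9 and 0.281 FPKM and Zeb1 at 37.4 and 3.98. Of 26 epithelial genes 24 were higher (median 3.51), with Epcam at 122 FPKM, Cdh1 at 63.1, Krt18 at 215 and Cldn6 at 79.4 in iPSCs. All 14 SRF target and contractile genes were lower (median -3.87), with Acta2 at 87.2 FPKM in iPSCs. Of 37 Hox genes found 14 were compared and 9 were lower (median -1.54, with no filter -0.30), such as Hoxa5 with 8.45 and 0.234 FPKM. Of 3 coding genes of the imprinted Dlk1-Dio3 region all were lower, with Dlk1 at 13.3 and 3.04 FPKM.

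Proliferation, glycolysis and DNA methylation genes were higher in iPSCs. Of 24 cell cycle genes 20 were higher than in MEFs (median 2.11), with Top2a at 60.8 and 460 FPKM and Ccnb1 at 25.6 and 182. Of 66 replication-dependent histone genes 60 were higher and 2 lower (median 2.36). Of 17 glycolysis genes 16 were higher (median 1.95), and the glucose transporter gene Slc2a3 was at 1.75 and 866 FPKM. Oxidative phosphorylation genes were mostly within the rule, with 3 of 16 higher (median 0.78). Of 8 DNA methylation enzymes 7 were higher, with Dnmt3l at 0.126 and 170 FPKM and Dnmt3b at 0.433 and 37.0, while Tet3 was within the rule at 3.07 and 1.55. Of 20 polycomb and chromatin genes 11 were higher and 1, Smarcc2, was lower with 23.3 and 4.41 FPKM. Of 82 ribosomal protein genes 20 were higher and 0 lower (median 0.81). Cholesterol biosynthesis genes were 6 higher and 1 lower of 18 against MEFs, and 11 higher of 18 against day 6.

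Some lists were lower or mixed in iPSCs. Of 13 interferon response genes 9 were lower than in MEFs (median -1.55), and of 11 macrophage and leukocyte markers 9 were lower (median -1.75) and 1, Laptm5, was higher with 4.31 and 38.5 FPKM. Of 16 p53 target and senescence genes 7 were lower and 1 higher. Cdkn2a was at 84.7 and 9.65 FPKM, and the proapoptotic gene Bbc3 at 8.14 and 43.5. Of 13 mitochondrially encoded genes 4 were lower and 1 higher (percentile 15.1). Rows of this list ranged in MEFs from 5.88 FPKM (mt-Nd4l) to 6222 (mt-Co1). Of 12 housekeeping genes 3 were lower and 1 higher, with a median of 0.23 (percentile 81.6) and a mean of -0.42. Actb was at 6059 and 1528 FPKM and B2m at 1478 and 42.3. In all, 2724 genes were higher and 3232 lower in iPSCs than in MEFs, of 12937 compared. The median over all of them was -0.045 as deposited and 0.125 after rescaling to the same upper quartile, when the counts were 3226 higher and 2826 lower.

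**Figure D3:**
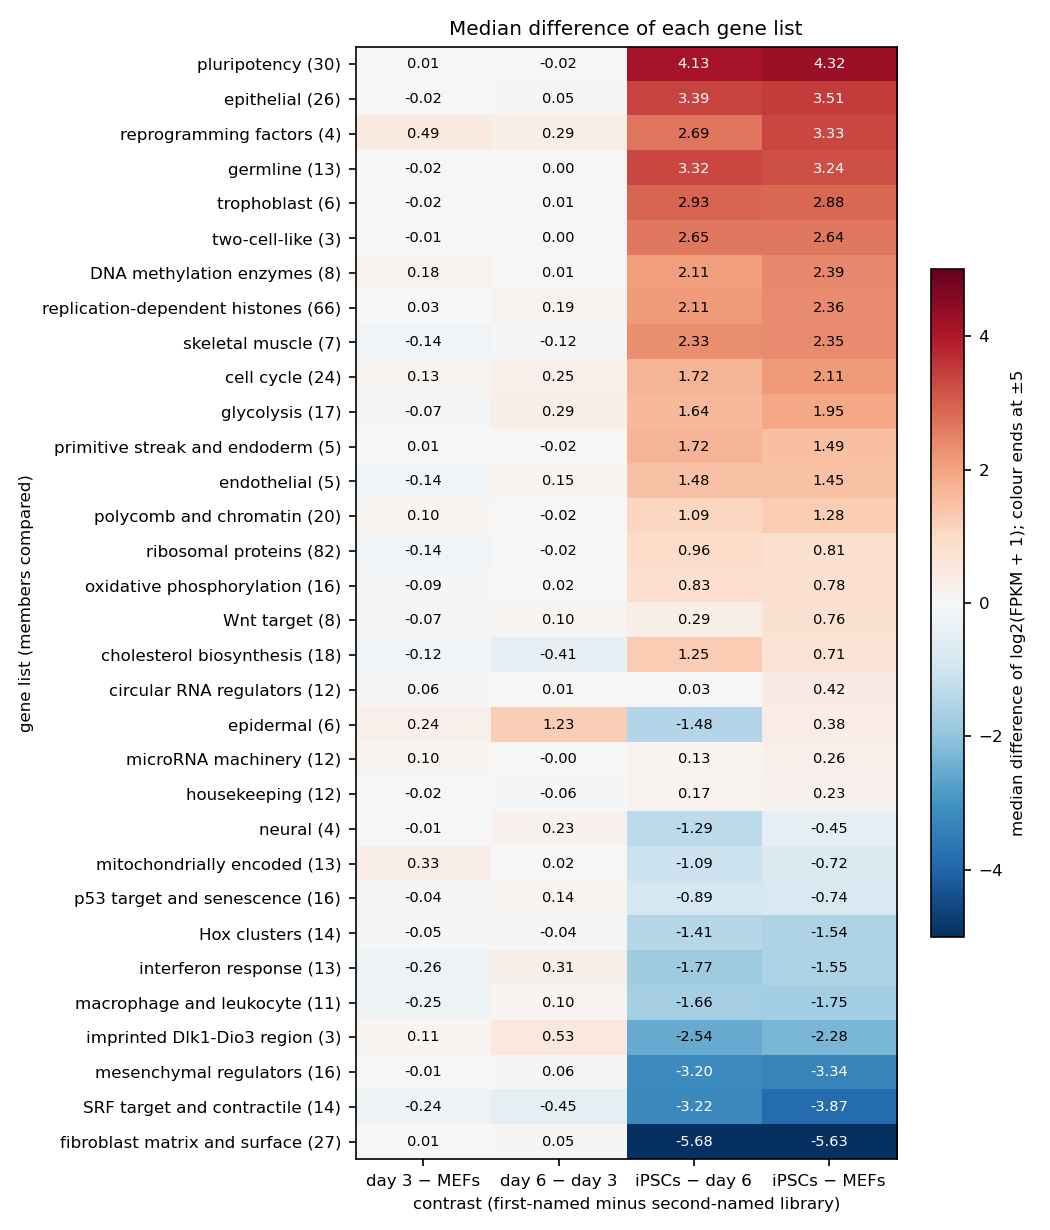
Median difference of log2(FPKM + 1) of each gene list (rows, with the number of members compared in parentheses) in 4 contrasts (columns), with red for higher and blue for lower in the first-named library and 1 library per group. The pluripotency list is at 0.01 and -0.02 in the day 3 and day 6 contrasts and at 4.32 for iPSCs against MEFs, the epidermal list is at 1.23 for day 6 against day 3, and the fibroblast list is at -5.63 for iPSCs against MEFs.

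RNA-processing lists were mostly within the rule. Of 12 genes of the microRNA machinery 2 were higher and 1 lower in iPSCs than in MEFs, with the nuclease gene Drosha at 11.1 and 26.8 FPKM, Zcchc11, a terminal uridylyl transferase that acts on let-7 precursors, at 5.77 and 21.1, and the Argonaute gene Eif2c3 at 12.8 and 4.73. Of 12 regulators of circular RNA formation 3 were higher and 2 lower. The splicing factor gene Mbnl1 was at 172 and 3.29 FPKM, Esrp1 at 0.0102 and 10.9, and Qk at 44.2 and 41.8. Between day 3 and MEFs and between day 6 and day 3 all members of both lists were within the rule. Of 64 rows matched to long noncoding RNA genes and compared, 17 were higher and 13 lower in iPSCs than in MEFs. Over all genes 46% were past the rule in that contrast. Of 45 compared between day 3 and MEFs, 0 were past the rule, and of 44 between day 6 and day 3, 1 was higher and 1 lower. Zfas1, the host of small nucleolar RNAs, was at 33.6, 30.6, 36.7 and 125 FPKM across the 4 stages (symbol 1500012F01Rik in the table).

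By the stage of highest expression, 6608 genes had a range of at least 1 across the 4 libraries. The highest value was in MEFs for 1635, at day 3 for 1026, at day 6 for 923 and in iPSCs for 3024. The first 3 of these classes are separated mostly by differences under the rule. At day 3 or day 6, 63 genes exceeded both MEFs and iPSCs by at least 1, of which 57 were highest at day 6 and 6 at day 3. By the stricter rule for transiently low genes, which needs both days, 0 were found. Genes low at day 6 alone were not counted, such as Mcam at 35.7, 29.3, 9.98 and 43.8 FPKM across the 4 stages. The counts depended on the pseudocount, with 117 high and 19 low at 0.1 and 21 high at 5. The transiently high genes, named after the values were seen, included Slurp1, Aldh3a1, Mal, Krt16, Krt14, Lcn2, Msln, Ahr, Srxn1 and Igfbp3.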

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

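The comparisons with day 6 against MEFs and without rows listed at 0 were chosen after seeing the data, and the other alternatives before. No call has a replicate check, the cause of each shift was not tested beyond what its construction shows, and low values were least precise in the shallower day 3 library. No paired analysis was possible because each group had 1 library, and leaving out a replicate was not possible for the same reason. The filter at 1 FPKM removes no call of the main rule, so the setting without it says nothing about the counts.

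All 24 counts under the 3 rescalings, and all 8 without rows listed at 0, stayed within 1.5 times the main count. The counts of the early contrasts moved most. For day 3 against MEFs (20 higher, 6 lower), a pseudocount of 0.1 gave 55 and 31, a pseudocount of 5 gave 6 and 2, a log2 difference of 2 gave 5 and 1, leaving out predicted, clone and short RNA names gave 13 and 3, and a minimum of 5 FPKM gave 12 higher. For day 6 against day 3 (54 and 47), the same pseudocounts gave 131 and 126, then 16 and 11, the log2 difference of 2 gave 5 and 1, the minimum of 5 FPKM gave 32 higher, and MEFs in place of day 3 gave 91 higher. With a pseudocount of 5, iPSCs had 1437 higher and 1842 lower genes against day 6 and 1502 and 1985 against MEFs, and with a log2 difference of 2 they had 880 and 1226, then 915 and 1279.

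For the stage of highest expression, a pseudocount of 0.1 gave 117 transiently high and 19 transiently low genes. A pseudocount of 5 gave 21 transiently high genes, with 587 highest at day 3, 508 at day 6 and 1663 in iPSCs, of 3851 in all. A log2 difference of 2 gave 11 transiently high genes, with 687 highest in MEFs, 381 at day 3, 368 at day 6 and 1008 in iPSCs, of 2444.

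Of 1056 list medians under alternatives, 961 moved by under 1.5-fold. Of the medians past the rule, 1 had another sign under an alternative, the neural list for iPSCs against day 6 (-1.29), which was 0.023 with no filter, when members near 0 enter. The moved medians follow for iPSCs against day 6 and then against MEFs. With a pseudocount of 0.1 they were pluripotency 6.86 and 6.98, fibroblast -6.35 and -6.25, mesenchymal -4.08 and -4.25, epithelial 5.03 and 5.37, interferon -3.40 and -2.94, germline 6.00 and 5.49, two-cell-like 5.75 and 5.62, streak 4.16 and 4.25, trophoblast 5.60 and 5.40, skeletal muscle 4.07 and 4.47, endothelial 2.15 and 2.81, macrophage -3.58 and -3.88, epidermal -3.12 and 1.03, Dlk1-Dio3 -4.04 and -4.15, Hox -3.14 and -3.31, and against MEFs alone reprogramming factors 4.07 and Wnt 1.44. With a pseudocount of 5 they were reprogramming factors 2.06 and 2.32, pluripotency 2.64 and 2.73, fibroblast -4.38 and -4.60, mesenchymal -2.25 and -2.18, epithelial 1.86 and 1.86, interferon -0.64 and -0.48, germline 1.52 and 1.503, two-cell-like 1.04 and 1.04, streak 0.56 and 0.50, trophoblast 1.25 and 1.24, skeletal muscle 0.96 and 0.92, endothelial 0.65 and 0.61, macrophage -0.52 and -0.56, Dlk1-Dio3 -1.77 and -1.19, Hox -0.43 and -0.49, and epidermal -0.54 against day 6. With no filter they were streak 0.35 and 0.35, trophoblast 1.77 and 1.75, skeletal muscle 0.75 and 0.73, endothelial 0.20 and 0.80, Hox -0.33 and -0.30, and epidermal -0.34 against day 6. With at least 5 FPKM they were trophoblast 3.58 and 3.54, skeletal muscle 3.23 and 3.53, endothelial 3.26 and 3.70, macrophage -2.86 and -2.65, Hox -2.58 and -2.94, epidermal -2.37 against day 6, and Wnt -0.38 against MEFs. With means they were DNA methylation 2.77 and 3.01, housekeeping -0.46 and -0.42, and glycolysis 2.31 against day 6. The epidermal list for day 6 against day 3 (1.23) was 2.02 and 0.54 with pseudocounts of 0.1 and 5 and 0.45 with no filter.

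With random lists not matched on expression, 8 of 132 percentiles crossed the limits of the central 95%. For iPSCs against day 6 and MEFs these were endothelial (98.7 and 98.3) and streak (99.4 and 98.5), for iPSCs against day 6 mitochondrially encoded (1.08) and p53 (1.73), and for day 3 against MEFs histones (97.2) and skeletal muscle (2.96).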

Other observations

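Lists of other lineages were described in few members, most of them near 0 in MEFs. Such genes enter a list only by reaching 1 FPKM in some library, here mostly iPSCs. The filter removes no call, but leaving out members near 0 raises the share called higher and moves the medians. The medians with no filter are therefore given beside. Of 15 germline genes found 13 were compared and were higher in iPSCs than in MEFs (median 3.24, with no filter 3.17), with Dazl at 0.0621 and 26.3 FPKM, and the meiotic gene Sycp3 at 0.669 and 20.3. The 3 genes found of the two-cell-like list were higher too, with Zscan4c at 5.28 FPKM. Of 6 trophoblast genes compared 5 were higher (median 2.88, with no filter 1.75), among them Tfap2c with 15.3 FPKM. Of 10 primitive streak and endoderm genes 5 were compared and 4 were higher (median 1.49, percentile 84.2, with no filter 0.35), with Gata4 at 8.74. Of 7 skeletal muscle genes compared 4 were higher (median 2.35, with no filter 0.73). The fast myosin light chain gene Mylpf was at 1.15 FPKM in MEFs and 377 in iPSCs, while Ckm was at 0.0987 in iPSCs. Of 5 endothelial genes compared 4 were higher and 1 lower (median 1.45, percentile 94.6, with no filter 0.80). Pecam1 was at 26.3 FPKM and Cdh5 at 0.202 in iPSCs. Of 4 neural genes 1 was higher and 2 lower (percentile 35.1), with Stmn2 at 29.1 and 97.6 FPKM. Of 8 Wnt target genes 4 were higher and 2 lower in iPSCs than in MEFs (percentile 75). At day 3 or day 6, 0 were past the rule, when Axin2 was at 1.11 and 1.57 FPKM.

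Among the mitochondrially encoded genes, mt-Nd4 was at 582 FPKM in MEFs and 1075 at day 3, and mt-Cytb at 2145 and 3211. Rows with no Ensembl identifier numbered 84, of which 59 were compared between iPSCs and MEFs, 18 higher and 5 lower, and 0 were past the rule at day 3 against MEFs.

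The list of 17 cartilage genes was added after 2 of its members, Col2a1 and Hapln1, had been seen. Without these, the 13 genes compared had a median of -0.68 for day 6 against day 3 at percentile 0, with 11 below day 3 and 0 past the rule, and 11 were lower in iPSCs than in MEFs. Col2a1, the collagen of cartilage, was at 740 FPKM in MEFs, 941 at day 3, 503 at day 6 and 1.79 in iPSCs, and Acan, the gene of aggrecan, at 29.3, 33.7, 17.8 and 1.11. Of all 15 members other than Col2a1 and Hapln1, with 2 that were not compared, 7 were at 10 FPKM or more in MEFs and 2 under 1, short of the majority set in advance on either side for cartilage cells in the culture.

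The 2 tests of Pou5f1 and Sox2 were chosen after the values they measure were seen, and the other tests before. For the genes apart at day 3, a bound had also to be passed by an exact binomial interval of 95%. That interval counts genes of the same libraries as independent trials, which they are not. For the aryl hydrocarbon receptor, a median over members that went both ways was taken to decide nothing. These requirements were applied after the values were seen, and they left open 3 tests that the bounds alone would have closed. Each pattern was found and tested on the same 4 libraries.

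Pou5f1 and Sox2 stood above MEFs at day 3 and day 6, and if a small share of cells with the whole iPSC profile carried them, other genes near absent from MEFs would show the same share. Pou5f1 implied 1.13% and Sox2 1.83% at day 6. The median over 34 genes under 1 FPKM in MEFs and at least 50 in iPSCs was 0.0135% (quartiles -0.0856% and 0.11%). These 34 genes include Pou5f1 and Sox2 themselves, which both lie above that median. The low median argues against a small share of cells with the whole iPSC profile. The genes at or above the Pou5f1 share were Krt8, Sox2, Cdh1 and Cldn4, the last an epithelial claudin at 0.0757 FPKM in MEFs and 0.982 at day 6. Other epithelial genes showed no such share (Epcam 0.0784%, Krt18 -0.159%, Cldn6 listed at 0 in MEFs and at day 6), and of the 26 epithelial genes compared 2 were higher at day 6 than in MEFs (median 0.02, percentile 69). Reads of the induced copies stay open. Increments at day 6 over the 4 factors (8.33 FPKM for Pou5f1, 1.62 for Sox2, 1.46 for Klf4 and 6.06 for Myc) differed by 5.71 times. FPKM scales reads to the length of the annotated gene, which need not be that of an induced copy. Equal induction thus need not give equal increments, so the ratio decides nothing, and the table does not separate the copies.

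At day 3, 11 genes were apart from both MEFs and day 6 by the rule, among them Rabl2 (5.25, 12.1 and 4.21 FPKM), Zfp35 and Zfp618. Fewer fragments in the day 3 library would act mostly on weak genes. Among genes of at least 20 FPKM, 2 were apart at day 3 only and 5 in MEFs only, a ratio of 0.4. It lay under the bound of 1.5 set for this explanation, but its interval (0.0381 to 2.44) also spans the bound of 2 set against it. Genes apart in MEFs only include any that changed by day 3 and stayed changed. Such genes lower the ratio at any depth, so a value under the bound does not speak for fewer fragments. Reads divided between overlapping gene models would favour genes that overlap another or share a symbol, which 6 of 9 with a reference entry did (66.7%, interval 29.9% to 92.5%, against 22.2% to 77.8% in matched sets). That share lay within the matched range set as the bound against it, but with 9 genes the test decides neither way. Rows of the symbol 2810453I06Rik were among these genes and moved in opposite directions at day 3. They were at 9.06, 0.238 and 8.72 FPKM and at 2.69, 10.6 and 1.95 FPKM in MEFs, at day 3 and at day 6. A division of reads between rows would give such a swap for that symbol. For the other genes neither source can be told apart from a difference of the culture, which was not tested.

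The genes higher at day 6 than at day 3 held several antioxidant and detoxification genes, for which a response of the transcription factor NRF2, whose trigger was not tested, is a candidate explanation. Over 20 NRF2 targets not used to form it, the median was 0.50 at percentile 100, with 19 of 20 above day 3. Of these targets 2 were past the rule, Txnrd1 (56.3 and 117 FPKM) and Gsta3 (0.117 and 1.46), and 18 were within it, such as Hmox1 (139 and 196). The shift of most was thus smaller than that of the genes to be explained. Those genes were picked for large differences, so the comparison of sizes decides nothing. For the aryl hydrocarbon receptor the 4 targets compared had a median of -0.16 at percentile 7.87, inside the bounds set in advance against this explanation, but 2 were above and 2 below day 3 (Ugt1a6a at 1.96 and 5.00 FPKM, Ahrr at 4.81 and 2.40), which leaves it open. Keratinocytes in the culture would bring abundant Krt14, which was at 4.66 FPKM at day 6 beside 67.9 for Slurp1, and the list of 5 abundant keratinocyte genes compared (median 0.26, percentile 99.5) shares Krt14, Trp63, Dsp and Perp with other lists, but Krt5 was not analysed here, so that source stays open.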
